A study of Gallus gallus with 24 samples.

How the data were processed

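Abdominal fat was taken from male broiler chickens of 2 lines selected in opposite directions for the weight of that fat depot, the fat line (FL) and the lean line (LL). Birds were 1, 3, 5, 7, 9 or 11 wk old. Total RNA of 4 birds per line and age was isolated on silica columns, per the labels' protocols, and its integrity was examined on a capillary electrophoresis chip. The cDNA carried Alexa Fluor 647 or Alexa Fluor 555 after indirect labelling. Each of the 24 spotted cDNA arrays held 1 FL bird and 1 LL bird of one age, with FL in the 647 channel on 2 arrays per age and LL in that channel on the other 2. The labels number the replicates 1 to 4, and each number stands for different birds, per the study's design text, so p-values measure the spread between birds and arrays together.

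The values used were the authors' deposited log2 ratios, 1 per spot and array, for 19200 spots. The submitters' processing notes name limma 3.4.5 and R 2.11.1. Background correction, normalization within or between arrays, spot filters and the sign convention were not given in the sources used here, and base 2 was taken from limma's usual output. Array medians lay between -0.056 and 0.019, close to 0, and whether the ratios were centred before deposit was not stated. The SD over spots of an array ran from 0.209 to 0.435, and single values from -5.34 to 6.91. On 1 array, 1 wk replicate 4, 160 spots had no value. Scanner intensities were not used here, so the signal over background behind a ratio is unknown, and the number of arrays sets the precision.

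Spots were named from the platform annotation, which lists spots by block, row and column. Of 19200 spots, 10601 had 1 gene symbol, 0 had several and 8599 had none. The gene identifiers of 10455 named spots (98.6%) were found in the RefSeq gene table of bGalGal1.mat.broiler.GRCg7b, used for names only, and it changed 0 symbols. The names were then checked against the values. Over 4958 pairs of spots that carry one gene in different clones, the mean within-array rank correlation was -0.0032 with the names as given, above 0 on 9 of 24 arrays. With row and column exchanged within each block it was 0.0533, above 0 on 23 of 24 arrays, and the next best of 228 distinct arrangements reached 0.0091. The exchanged names were used, a choice made after seeing the data, and results with the names as given are in the part on processing. These correlations are across spots, which are not independent replicates.

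The direction of the ratios was examined next. Arrays of one dye orientation correlated at a mean r of 0.213 across spots (lowest -0.179), and arrays of opposite orientation at -0.170. The design fixed beforehand would turn such ratios by the dyes. They were nevertheless left as deposited, a departure decided after seeing the data on the following measurements. Each spot's ratio was parted into a component common to all arrays and one that alternates with the dye orientation. Over 1004 spots of 472 clones printed several times, the intraclass correlation between copies of a clone was 0.248 for the common component and 0.119 for the alternating one, although the alternating one repeated better between arrays (split reliability 0.815 against 0.444). For the 2 control clones, printed on 94 and 29 spots, the alternating component varied between copies 8.90 and 12.8 times more than its error allowed, against 1.25 and 0.638 times for the common one. Over all spots these values were 6.85 for the alternating and 1.30 for the common component. The common component thus varied little between different genes as well, so its low values between copies do not show that it repeats by clone. The largest number of significant digits written per value also differed, 6 on arrays with LL in the 647 channel and 10 on the others. An ATP1B1 clone went the other way, since the alternating component lay below 0 on all 10 of its copies (-0.448 to -0.013) and the common one above 0 on 9 of 10. For a GAPDH clone the alternating component lay above 0 on 2 of 9 copies (-0.542 to 0.095) and the common one on 8 of 9. The alternating component thus repeated by clone in part, as a gene's own dye bias or a line difference would. It was fitted as a dye term, and the choice is not settled by these values. Which line is the numerator is not stated. The titles name FL first, so FL is the likely numerator, and "higher" below means higher in the numerator line. Every sign turns if LL was the numerator, and all counts stay. Results with the ratios turned by the dyes stand beside the dye effect.

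The 123 spots of the 2 control clones were left out. Spots of one gene symbol were averaged, without regard to whether they differed, and unnamed spots stayed single. This gave 15027 features, 6428 of them named and 2770 of these from several spots, each with a value on at least 3 of the 4 arrays of every age, and 75 features lacked a value on some array.

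Ratios were fitted in limma 3.58.1 (R 4.3.3, statmod 1.5.0) with 6 age-specific line effects and a gene-specific dye effect over all 24 arrays, which share one estimate of the spread, followed by eBayes. Contrasts were the mean over the 6 ages, each age, a linear trend per week of age, and a moderated F test that the 6 effects are equal. Tests were two-sided, and adjusted p-values are Benjamini-Hochberg values over all features, called at 0.05. The age effect itself could not be tested, since both birds on an array had one age. Tables and plots were made in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.

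Gene lists were tested with camera at a preset correlation of 0.01, adjusted over the lists with at least 5 genes measured on all arrays, and again with an estimated correlation. Fry, whose p tests whether a list's genes move one way on balance and whose mixed p tests change in either direction, was run beside it. For each list the count called "adjusted over the list alone" was also taken. The theme of the hemostasis list is known from the study's own paper, so that list is not independent of these samples. Genes were named by a rule: called genes of one sign in at least 20 of 24 arrays in the mean over ages, up to 13 each way, and up to 4 each way at each age, up to 8 in the trend and the interaction, and up to 6 per list. Where fewer were called all were to be named, and where none were, the 3 smallest p-values of a comparison or the 2 smallest of a list, given as not called. FASN, SCD, ACACA, THRSP, ADIPOQ and PPARG were added wherever lipogenesis is described. ME1 and LPL were on the rule's list and had no named spot here. Further genes given below as examples of a list, such as COL6A3, COL5A1, FABP4, ACSL1, NDUFA9 and HSPA8, lie outside this rule. They were chosen after their values were seen, mostly in the direction of the list. They were not followed through the other settings, so they are illustrations and no evidence beyond the list.

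The groups, the tests, the lists, the rule for named genes and most alternatives were fixed before the data were examined. These alternatives were no dye term, a replicate block, centring, scaling, array weights, other filters on missing values, single spots, a robust prior, single ages or arrays left out, the 4 arrays of one age alone, other age models, and the estimated correlation. Added after seeing the data were the names as given, ratios turned by dye, loess over the position within each block with a span of 0.4 with and without medians per printed position, removal of each array's own dye bias, and fits without the arrays that stood apart.

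The fit was tested on simulated data with 100 features changed at each size among 14952. Normal noise was drawn independently, with 1 SD per feature and the same dye effect on all arrays. The measured arrays differed in weight (0.404 to 3.47) and in the size of their dye bias (0.023 on 3 wk replicate 2, 1.36 on 9 wk replicate 2). The rates below therefore describe the simulated setting and may not hold for the measured arrays. In the mean over ages, 76 of 100 changes of 0.25 and 99 of 100 of 0.5 were recovered with 10 false calls. At 7 wk, 61 of 100 changes of 0.5 and 98 of 100 of 1 were recovered, with 7 false calls. For the interaction 22 of 100 of 0.5 and 82 of 100 of 1 were recovered, with 6 false calls, and for the trend 37 of 100 of 0.05 per week and 94 of 100 of 0.1, with 6 false calls. A shift of 0.06 placed on the 42 extracellular matrix genes tested gave an adjusted p of 2.14e-14 with camera and 6.53e-06 with an estimated correlation, with 0 other lists called. This was a single simulated case. Power was not examined over the correlations estimated in the measured lists, such as 0.0694 for the matrix, 0.198 for ribosomal proteins and 0.338 for hepatocytes.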

Results

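The 24 arrays compared abdominal fat of a fat line bird with that of a lean line bird, 4 arrays at each of 6 ages, in chickens bred for a large or small abdominal fat depot. Each value was read as a log2 ratio of the numerator line over the denominator line for 15027 features, of which 6428 carried a gene symbol. The dye checks did not settle this reading. If the ratios had to be turned by the dyes, the counts and list results would change too, as given with the dye effect. The ratios had no depth attached, and the 4 arrays per age limited the precision. The median standard error (SE) of a line effect was 0.0443 over the 6 ages and 0.108 to 0.109 at a single age. FL was likely the numerator, since the titles name it first, but this was not settled, and every sign below turns if LL was.

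The mean over the 6 ages asked which transcripts differed between the lines over juvenile growth as a whole. The extracellular matrix list was higher in the numerator line: 33 of its 43 measured genes lay above 0, with a median log2 ratio of 0.041 (camera adjusted p 4.61e-06, and adjusted p = 0.189 with an estimated correlation). The list's median lay above 0 on 20 of 24 arrays, but at 5 wk it was -0.0088 (21 of 43 genes above 0). Its largest ratios belonged to POSTN, a matricellular protein of connective tissue, at 0.50 (SE 0.108, above 0 on 21 of 24 arrays), and to COL6A3, a chain of collagen VI, at 0.43 (SE 0.113). COL5A1, a chain of collagen V, stood at 0.32 (SE 0.0778). FN1, which encodes fibronectin, stood at 0.14 as the mean of 6 probes (SE 0.0336, above 0 on 20 of 24 arrays). With probes kept single, 1 FN1 spot stood at 0.53 (SE 0.073, adjusted p 0.00661) and was the only one called of 19077. The ribosomal protein list was higher as well, with 38 of 44 genes above 0 and a median of 0.064 (adjusted p 4.18e-06, and adjusted p = 0.69 with an estimated correlation, above 0 on 17 of 24 arrays). Its median was -0.0063 at 7 wk (21 of 44) and -0.06 at 9 wk (18 of 44). It was led by RPS24 at 0.45 (SE 0.102) and RPL17 at 0.36 (SE 0.0921). Skeletal muscle markers were lower, with 8 of 35 genes above 0 and a median of -0.031 (adjusted p 0.0109, and adjusted p = 0.69 with an estimated correlation, above 0 on 6 of 24 arrays). Among them were the sarcomere gene TTN at -0.20 (SE 0.0851) and TRDN, a protein of the calcium release complex, at -0.11 (SE 0.0308).

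No single feature passed limma's adjusted p of 0.05 in the mean over ages: 0 were called, and 1067 had an unadjusted p under 0.05 where 751 were expected by chance. The same 751 are expected in each other comparison. Fewer were found at 1 wk (401), 5 wk (437), 7 wk (471) and 11 wk (200), in the trend (366) and the interaction (342). Array weights ran from 0.404 (7 wk replicate 1) to 3.47 (11 wk replicate 2). Whether the shared estimate of the spread distorts these p-values was not tested. The 3 named genes with the smallest p were ADD3 (0.26, SE 0.0494, adjusted p 0.139, above 0 on 19 of 24 arrays), SULT6B1L (0.42, SE 0.0817, adjusted p 0.139, 20 of 24 arrays) and GPR183 (0.54, SE 0.108, adjusted p 0.171, 20 of 24 arrays). ADD3 encodes gamma-adducin of the membrane skeleton, SULT6B1L a sulfotransferase, and GPR183 an oxysterol receptor of immune cells. Adjusted over the list alone, 8 extracellular matrix genes, 4 ribosomal protein genes and 1 skeletal muscle gene passed, against 0 of each over all features. At an unadjusted p under 0.05, 11 matrix genes were higher and 0 lower, 9 ribosomal protein genes higher and 1 lower, and 0 muscle genes higher and 3 lower. As a mean score per array, tested in limma over the 30 lists, the matrix list stood at 0.08 (adjusted p 0.0243), ribosomal proteins at 0.09 (0.408) and skeletal muscle at -0.05 (0.524). Fry's mixed test, for change in either direction, was passed by 1 list, the extracellular matrix (adjusted p 0.000697), and its directional test by 0. Leaving out 5 wk replicate 2 raised the count of called features from 0 to 100, the most of the 24 omissions. These included GPR183 (adjusted p 0.00118), RPS24 (0.00369), RPL17 (0.0106), SULT6B1L (0.0124), ARHGDIB (0.0213), ADD3 (0.0257), POSTN (0.0265), FN1 (0.0363) and SLC25A20 (0.0363). On the omitted array the dye-corrected ratios of GPR183 (-1.60), POSTN (-0.53) and FN1 (-0.16) opposed their means over ages, while ADD3 (0.52) did not. These p-values therefore come from the most favourable omission. All 27 lower unnamed spots called there lay in 1 column of blocks on the array. Leaving out 1 wk replicate 2, 1 wk replicate 4 or 9 wk replicate 2 gave 4, 1 and 1 called features, POSTN and SULT6B1L (0.0348 each) among the 4. The skeletal muscle call was lost without 3 wk replicate 1 (adjusted p 0.0503), 7 wk replicate 4 (0.285) or 9 wk replicate 3 (0.0971), and without the age of 7 wk (0.0825). It was also lost without both 1 wk replicate 2 and 5 wk replicate 1 (0.0829). The list's median stood at -0.016 without 1 wk replicate 3 and at -0.020 without 7 wk replicate 4.

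**Figure D1:**
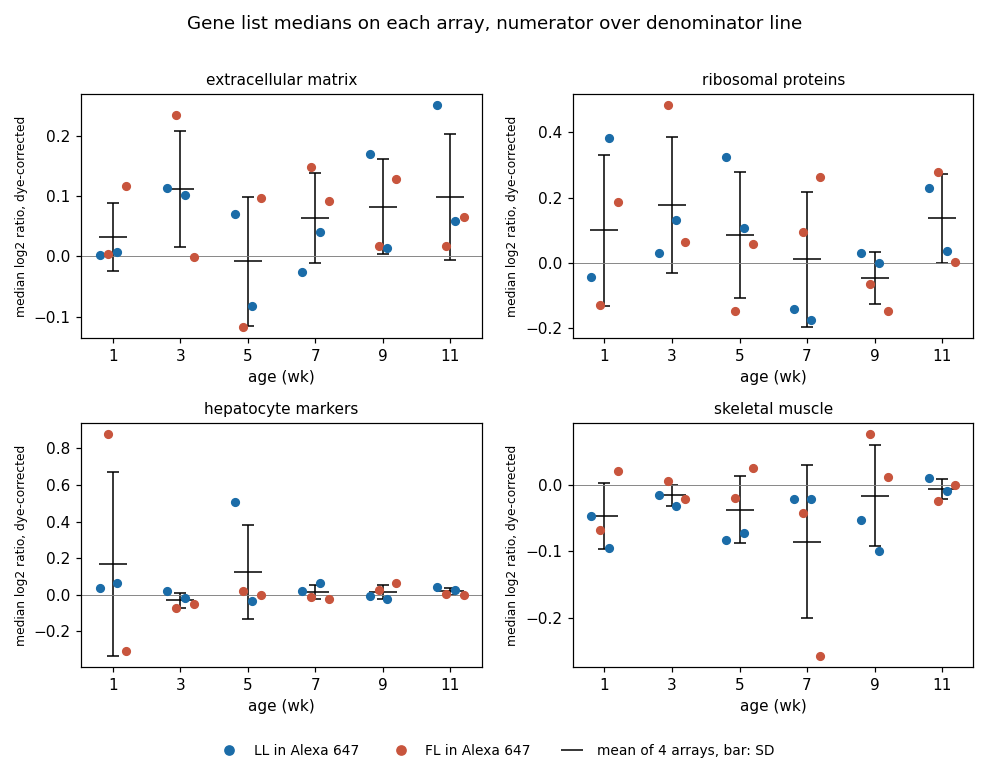
Dye-corrected median log2 ratio (numerator over denominator line, vertical axis) of 4 gene lists on each array, against age in weeks (horizontal axis); blue points are arrays with LL in Alexa 647, red points arrays with FL in Alexa 647, and black dashes with bars give the mean of the 4 arrays of an age ± SD. The extracellular matrix medians lie above 0 on 20 of 24 arrays and the ribosomal protein medians on 17, the hepatocyte list reaches 0.877 on 1 array of 1 wk and 0.508 on 1 of 5 wk, and the skeletal muscle list lies at -0.258 on 1 array of 7 wk.

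The genes of fat synthesis and storage lay close to 0 in the mean over ages. FASN, the fatty acid synthase, stood at 0.01 (SE 0.0411), ACACA, which makes malonyl-CoA, at 0.0043 (SE 0.0364) and SCD, the stearoyl-CoA desaturase, at -0.10 (SE 0.0662). THRSP, a lipogenic regulator, stood at -0.06 (SE 0.0853), PPARG, the transcription factor of adipocyte differentiation, at 0.04 (SE 0.0985) and ADIPOQ, which encodes adiponectin, at -0.0021 (SE 0.0473). None of these 6 was called (adjusted p 0.848 to 1). The signs of FASN, ACACA, THRSP, PPARG and ADIPOQ turned under at least 1 other setting. Of the 28 measured genes of fatty acid synthesis 17 lay above 0 (median 0.010, adjusted p 0.934), with ELOVL1 at -0.09 and FADS1 at 0.05 nearest to a call. Triglyceride storage had 8 of 19 above 0 (median -0.016, adjusted p 0.63), with the fatty acid transporter SLC27A4 at 0.12 and the lipoprotein receptor VLDLR at -0.13. Sterol synthesis had 7 of 15 (median -0.016, adjusted p 0.834), with its regulator SREBF2 at -0.09 and HSD17B7 at -0.07. Lipolysis had 3 of 9 (median -0.023, adjusted p 0.92), with the monoglyceride lipase MGLL at 0.09 and the lipase inhibitor G0S2 at -0.16. Fatty acid oxidation had 19 of 28 above 0 (median 0.019, adjusted p 0.337), with the carnitine carrier SLC25A20 at 0.15 (SE 0.0399) and the acyl-CoA dehydrogenase ACADL at -0.14 (SE 0.0396). Of its genes 2 passed adjusted over the list alone against 0 over all features.

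Other regulatory and metabolic lists did not pass either. Adipogenic regulators had 14 of 24 above 0 (median 0.0019, adjusted p 0.834), with EBF2 at 0.16 (SE 0.0391) and EBF3 at 0.09, and 1 gene passed adjusted over the list alone against 0 over all features. Adipokines had 9 of 24 (median -0.017, adjusted p 0.834), with RARRES2, which encodes chemerin, at 0.12 and RBP4, the plasma retinol carrier, at -0.21. Retinoid metabolism had 9 of 18 (median -0.0013, adjusted p 0.92), with the cellular retinol-binding gene RBP7 at 0.21. The thyroid axis had 4 of 11 (median -0.010, adjusted p 0.92), with NCOR1 at 0.10 and the receptor THRB at -0.06. Glucose metabolism had 13 of 29 (median -0.0044, adjusted p 0.92), with the glycolytic ALDOC at -0.06 and PFKFB1 at 0.07. Insulin and IGF signalling had 7 of 16 (median -0.0046, adjusted p 0.92), with the binding protein IGFBP2 at -0.16 and IGF2BP3 at 0.04. Hemostasis, whose theme came from the study's own paper and is not independent evidence, had 19 of 28 (median 0.024, adjusted p 0.552), with the protease inhibitor SERPINE2 at 0.22 and the clotting factor gene F13A1 at 0.09. Cell cycle genes had 20 of 35 (median 0.0025, adjusted p 0.92), with CCND1 at 0.19 and KIF2C at -0.19. Mitochondrial respiration had 21 of 42 (median -0.00059, adjusted p 0.92), with ATP5O at 0.13 and COX17 at -0.08. Immediate early and stress genes had 13 of 18 (median 0.019, adjusted p 0.337), with JUN at 0.13 and the chaperone HSP90B1 at 0.14.

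Markers of immune, vascular and other cells did not pass in the mean over ages. The interferon response had 12 of 19 above 0 (median 0.0066, adjusted p 0.63), with IRF1 at 0.18 (SE 0.0515, above 0 on 21 of 24 arrays) and B2M at 0.09. Macrophage genes had 15 of 21 (median 0.022, adjusted p 0.337), with IL1B at 0.13 and LYG2 at 0.28. General leukocyte genes had 7 of 13 (median 0.0019, adjusted p 0.92), with ARHGDIB at 0.17 and LCP1 at -0.09. T cell genes had 2 of 6 (median -0.018, adjusted p 0.92), with IL2RG at -0.08 and IL2RA at 0.12. The B cell list, with ARHGDIB again and CD40 at 0.04, held too few fully measured genes for camera, and its mean score of 0.04 had an adjusted p of 0.425 in limma. Erythrocyte genes had 8 of 13 above 0 (median 0.0018, adjusted p 0.956), with the globin HBBA at 0.09 and EPB41 at -0.05. Smooth muscle had 10 of 21 (median -0.0028, adjusted p 0.92), with ACTA2 at -0.10 and LMOD1 at 0.12. Endothelium had 10 of 25 (median -0.0021, adjusted p 0.92), with ECSCR at 0.10 and ROBO4 at 0.09. Mesothelium had 7 of 11 (median 0.0031, adjusted p 0.962), with CALB2 at -0.04 and LRRN4 at 0.11. Exocrine pancreas and gut had 4 of 8 (median -0.018, adjusted p 0.63), with CELA1 at -0.09 and CPA1 at -0.10. Nerve and glia had 9 of 15 (median 0.0065, adjusted p 0.92), with S100B at -0.23 and SOX10 at 0.11. Hepatocyte markers had 27 of 32 above 0 (median 0.071, adjusted p 0.0696), although the genes with the smallest p, LECT2 and CYP2C18, stood at -0.22 and -0.21. Without the 2 arrays with high liver genes (1 wk replicate 2 and 5 wk replicate 1) the hepatocyte median turned to -0.01 (adjusted p 0.697). It was called with each array's own dye bias taken off (0.07, adjusted p 0.0296, and adjusted p = 0.913 with an estimated correlation) and without 7 wk replicate 4 (0.07, adjusted p 0.0449, and adjusted p = 0.977 with an estimated correlation). Adjusted over the list alone, 1 gene of the interferon list, 1 of the leukocyte list and 3 of the nerve and glia list passed, against 0 over all features. Camera's direction was opposite to the list's median for mitochondrial respiration, erythrocytes and mesothelium, and the mean of the thyroid axis and smooth muscle lists lay above 0 with a median below it. Single arrays carried much of some values in the mean over ages. IL2RA stood at 0.0060 without 9 wk replicate 4, B2M at 0.05 and HSP90B1 at 0.09 without 3 wk replicate 2, LRRN4 at 0.06 without 5 wk replicate 1 and LMOD1 at 0.07 without 5 wk replicate 3. Without 1 wk replicate 4 CPA1 stood at -0.06 and IL2RG at -0.05, without 3 wk replicate 4 THRB at -0.03 and CYP2C18 at -0.14, without 1 wk replicate 1 G0S2 at -0.07, without 9 wk replicate 4 MGLL at 0.06 and without 7 wk replicate 4 TTN at -0.12.

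At 1 wk, the youngest age, 6 lists were higher in the numerator line and 1 lower. Triglyceride storage genes were higher, 15 of 19 above 0 with a median of 0.09 (adjusted p 0.00538, and adjusted p = 0.261 with an estimated correlation), led by the fatty acid-binding protein gene FABP4 at 0.78 (SE 0.369) and the acyltransferase GPAT3 at 0.32 (SE 0.15). Fatty acid synthesis genes were higher, 22 of 28 with a median of 0.05 (adjusted p 0.00817, and adjusted p = 0.265 with an estimated correlation), led by the acyl-CoA synthetase ACSL1 at 0.75 (SE 0.341). Mitochondrial respiration genes were higher, 28 of 42 with a median of 0.07 (adjusted p 0.00242, and adjusted p = 0.261 with an estimated correlation), with NDUFA9 of complex I at 0.45 (SE 0.166) and UQCRQ of complex III at 0.41 (SE 0.124). Smooth muscle genes were lower, 5 of 21 above 0 with a median of -0.07 (adjusted p 0.0152, and adjusted p = 0.261 with an estimated correlation), with the myosin light chain kinase gene MYLK at -0.21 and the myosin gene MYL9 at -0.19.

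Ribosomal protein genes were also higher at 1 wk, 36 of 44 with a median of 0.08 (adjusted p 0.000676, and adjusted p = 0.426 with an estimated correlation), with RPS23 and RPLP0 at 0.39 each. Hepatocyte markers were higher, 25 of 32 with a median of 0.15 (adjusted p 0.000574, and adjusted p = 0.451 with an estimated correlation), and hemostasis genes were higher, 20 of 28 with a median of 0.06 (adjusted p 0.00307, and adjusted p = 0.261 with an estimated correlation). These 2 lists share genes made in liver, such as FGB, which encodes fibrinogen beta, at 0.84 (SE 0.491). They moved with single arrays. The dye-corrected hepatocyte median was 0.877 on 1 wk replicate 2 and -0.311 on 1 wk replicate 4, and without replicate 2 the hepatocyte list at 1 wk turned to -0.12 (adjusted p 0.00157) and the hemostasis list to -0.02 (adjusted p 0.968). Without this array and 5 wk replicate 1 the hepatocyte list stood at -0.11 (adjusted p 0.00057, and adjusted p = 0.308 with an estimated correlation). The fatty acid synthesis call also ended without replicate 2 (adjusted p 0.326) and replicate 4 (0.246), and the triglyceride storage call without replicate 4 (0.876). With both of these and 5 wk replicate 1 left out, a setting chosen after seeing the data, the direction of both lists at 1 wk turned, to -0.02 for triglyceride storage (adjusted p 0.795) and -0.05 for fatty acid synthesis (0.642). All arrays of 1 wk kept in that setting had LL in the 647 channel. The line effect at 1 wk then depends on the dye effect estimated at the other ages. The turn therefore cannot be told apart from dye bias.

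No single feature was called at 1 wk by limma (0 called, 401 with an unadjusted p under 0.05), and 0 genes of the 7 lists passed adjusted over the list alone or over all features. The 3 named genes with the smallest p, each of one sign on 4 of 4 arrays and each with an adjusted p of 1, were PARD3B, a cell polarity gene, at -0.44 (SE 0.0959), the glutathione transferase GSTA2 at 0.33 (SE 0.0755) and the replication licensing gene CDT1 at -0.34 (SE 0.0786). FASN stood at 0.16 (SE 0.101), SCD at 0.04 (SE 0.162), ACACA at -0.07 (SE 0.0892), THRSP at 0.40 (SE 0.209), PPARG at 0.40 (SE 0.241) and ADIPOQ at -0.22 (SE 0.116), none of them called. Without replicate 4, THRSP stood at -0.02, SCD at -0.09 and PPARG at 0.09, without replicate 2 FASN at 0.02 and ADIPOQ at -0.35, and without replicate 1 ACACA at -0.0089. With 5 wk replicate 2 left out, 1 feature was called at 1 wk. The number of lists was 7 with all arrays and 4 without 1 wk replicate 3 or replicate 4. Without replicate 3 the mitochondrial, smooth muscle and ribosomal protein lists had adjusted p-values of 0.34, 0.377 and 0.94. Without replicate 4 the mitochondrial list had 0.0919, and without replicate 1 the smooth muscle list had 0.138.

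At 3 wk 3 lists were higher in the numerator line and 0 lower. Ribosomal protein genes were higher, 36 of 44 with a median of 0.15 (adjusted p 4.84e-06, and adjusted p = 0.8 with an estimated correlation), with the ribosome-associated RACK1 at 0.63 (SE 0.155) and RPL3 at 0.62 (SE 0.234). Extracellular matrix genes were higher, 31 of 43 with a median of 0.07 (adjusted p 0.0128, and adjusted p = 0.8 with an estimated correlation), with COL6A3 at 0.85 (SE 0.276), COL5A1 at 0.63 (SE 0.191) and the proteoglycan gene DCN at 0.62 (SE 0.209). COL4A1, a basement membrane collagen of the same list, stood at -0.56 (SE 0.136). Immediate early and stress genes were higher, 15 of 18 with a median of 0.15 (adjusted p 0.0196, and adjusted p = 0.8 with an estimated correlation), with the transcription factor JUN at 0.42 (SE 0.112) and the chaperone HSPA8 at 0.34 (SE 0.257). Adjusted over the list alone, 1 gene of each of these 3 lists passed, against 0 over all features. limma called 0 features, and 1033 had an unadjusted p under 0.05. The smallest p of named genes belonged to the translation factor EIF1B at -0.40 (SE 0.0879), the repressor ZBTB32 at -0.53 (SE 0.125) and the histone demethylase gene PHF2 at -0.49 (SE 0.118), each below 0 on 4 of 4 arrays with an adjusted p of 0.272. ZBTB32 stood at -0.33 without 3 wk replicate 4 and PHF2 at -0.31 without replicate 2. All 3 list calls at 3 wk were lost without 3 wk replicate 2 (adjusted p 0.239, 0.239 and 0.644), where the medians of ribosomal proteins, matrix and stress genes were 0.06, 0.05 and 0.05, and that of the stress genes without replicate 4 (0.0887). With each array's own dye bias taken off, 0 lists were called at 3 wk, where ribosomal proteins stood at 0.08 (adjusted p 0.0991), matrix genes at 0.06 (0.145) and stress genes at 0.04 (0.173). The count of features was 18 without 3 wk replicate 1 (PHF2 among them, adjusted p 0.0461), 1 without 5 wk replicate 4, and 182 with array weights, 147 of them lower.

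At 5 wk the ribosomal protein genes were higher, 31 of 44 with a median of 0.10 (adjusted p 0.0117, and adjusted p = 0.83 with an estimated correlation), with RPS24 at 1.01 (SE 0.25) and RPL17 at 0.47 (SE 0.226). Hepatocyte markers were higher, 26 of 32 with a median of 0.11 (adjusted p 0.0268, and adjusted p = 0.83 with an estimated correlation), with the serum albumin gene ALB at 1.03 (SE 0.581) and FGB at 0.53 (SE 0.491). On 5 wk replicate 1 the dye-corrected hepatocyte median was 0.508, against -0.035 to 0.020 on the other 3 arrays. Without replicate 1 neither list was called (adjusted p 0.998 for hepatocytes and 0.969 for ribosomal proteins), and the ribosomal protein median was -0.0054. limma called 0 features, and 437 had an unadjusted p under 0.05. The smallest p of named genes belonged to RBBP6, an RB1-binding ubiquitin ligase, at -0.58 (SE 0.125), the carboxylesterase CES1L1 at 0.53 (SE 0.126) and VCAM1, a vascular adhesion receptor of leukocytes, at 0.49 (SE 0.12), each of one sign on 4 of 4 arrays with an adjusted p of 1. Adjusted over the list alone, 1 ribosomal protein gene and 0 hepatocyte genes passed, against 0 over all features. The hepatocyte call was lost without replicate 2 (0.106) and the ribosomal protein call without replicate 3 (0.0702) or replicate 4 (0.112), and 5 features were called without replicate 2.

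At 7 wk 1 feature was called: NECAB2, which encodes a neuronal calcium-binding protein, was lower by a log2 ratio of -0.43 (SE 0.0614, adjusted p 0.00918, below 0 on 4 of 4 arrays), while at the other ages it lay between -0.04 and 0.01. Extracellular matrix genes were higher, 35 of 43 with a median of 0.09 (adjusted p 0.000437, and adjusted p = 0.472 with an estimated correlation), with COL6A3 at 0.33 (SE 0.276) and COL5A1 at 0.26 (SE 0.191). Skeletal muscle markers were lower, with 6 of 35 above 0 and a median of -0.08 (adjusted p 0.00117, and adjusted p = 0.472 with an estimated correlation), among them the sarcomere genes TTN at -0.66 (SE 0.208), MYL1 at -0.60 (SE 0.218) and TNNT3 at -0.58 (SE 0.251). The muscle list stood at -0.258 on 7 wk replicate 4 and between -0.042 and -0.021 on the other 3 arrays, and without replicate 4 its median at 7 wk was -0.01 with camera's direction upward (adjusted p 0.848). In all, 471 features had an unadjusted p under 0.05, and adjusted over the list alone 0 genes of either list passed, as over all features. NECAB2 was not called without 7 wk replicate 1 (adjusted p 0.0624, 2 other features called), replicate 2 (0.0656) or replicate 3 (0.21), although its ratio stayed between -0.48 and -0.39 with any array left out. Nor was it called with the 4 arrays of 7 wk alone (1) or after position loess (-0.25, adjusted p 0.558), and it rested on 1 spot. The matrix call was lost without replicate 2 (0.0556), which left 1 list.

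**Figure D2:**
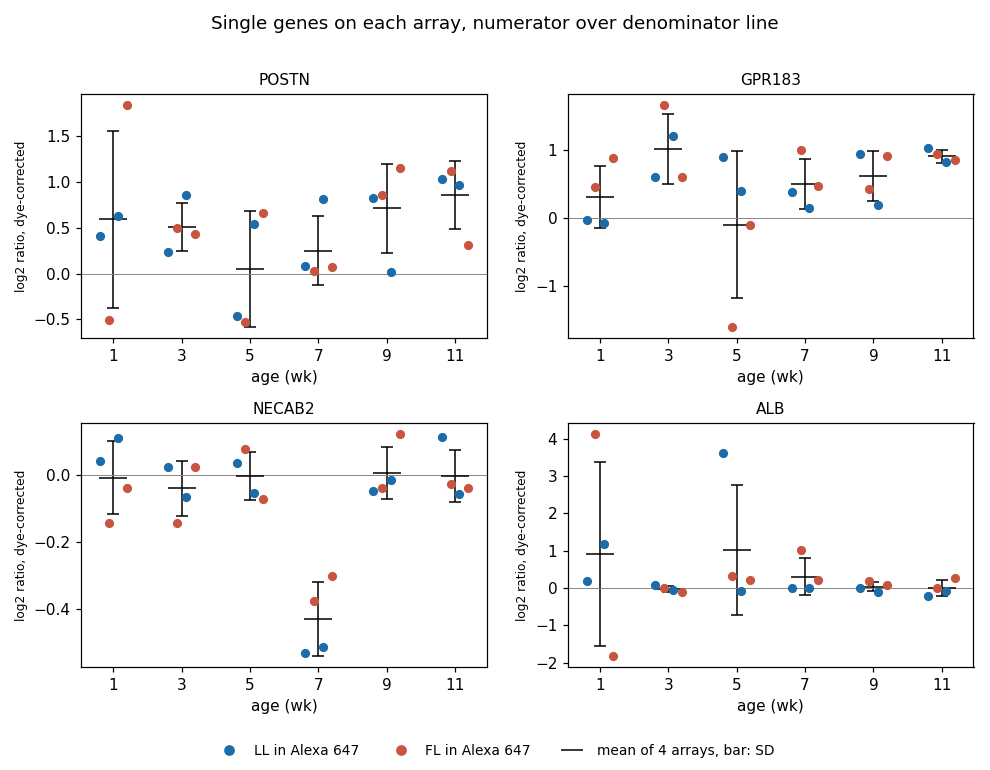
Dye-corrected log2 ratios (numerator over denominator line, vertical axis) of POSTN, GPR183, NECAB2 and ALB on each array, against age in weeks (horizontal axis), in blue with LL in Alexa 647 and in red with FL in Alexa 647; black dashes with bars are the mean of 4 arrays ± SD. NECAB2 lies between -0.53 and -0.30 on the 4 arrays of 7 wk, GPR183 lies at -1.60 on 1 array of 5 wk, and ALB reaches 4.12 on 1 array of 1 wk and 3.63 on 1 of 5 wk.

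At 9 wk no list and no feature was called. POSTN stood at 0.71 (SE 0.265), COL6A3 at 0.42 (SE 0.276) and the proteoglycan gene LUM at 0.40 (SE 0.164), and 29 of 43 extracellular matrix genes lay above 0 (median 0.07, adjusted p 0.241). With each array's own dye bias taken off, this list was called (0.08, adjusted p 0.0278, and adjusted p = 0.919 with an estimated correlation). Mitochondrial respiration genes lay mostly below 0, 17 of 42 above (median -0.05, adjusted p 0.241), with NDUFA9 at -0.31 (SE 0.166), and so did triglyceride storage, 6 of 19 above (median -0.05, adjusted p 0.335). limma called 0 features and 1329 had an unadjusted p under 0.05, against 751 expected by chance. The smallest p of named genes belonged to MKLN1, which encodes muskelin, at -0.37 (SE 0.0756), and the growth regulator PHLDA2 at -0.39 (SE 0.0853). Next came the nuclear matrix gene BANP at -0.45 (SE 0.10). Each of these genes lay below 0 on 4 of 4 arrays with an adjusted p of 0.356. Adjusted over the list alone, 0 matrix, 0 mitochondrial and 1 triglyceride storage genes passed, against 0 over all features.

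At 11 wk the extracellular matrix and ribosomal protein lists were higher in the numerator line. Of the matrix genes 31 of 43 lay above 0 with a median of 0.09 (adjusted p 3.31e-05, and adjusted p = 0.311 with an estimated correlation), with POSTN at 0.86 (SE 0.265) and COL6A3 at 0.46 (SE 0.276). Of the ribosomal protein genes 39 of 44 lay above 0 with a median of 0.13 (adjusted p 7.88e-07, and adjusted p = 0.44 with an estimated correlation), with RPS24 at 0.76 (SE 0.25) and RPL11 at 0.44 (SE 0.208). The smallest p of single genes belonged to GPX3, the plasma glutathione peroxidase, at 0.57 (SE 0.143), GPR183 at 0.91 (SE 0.264) and POSTN, each above 0 on 4 of 4 arrays with an adjusted p of 1. limma called 0 features (200 with an unadjusted p under 0.05), and adjusted over the list alone 0 genes of both lists passed, as over all features. The matrix median was 0.03 without 11 wk replicate 1 (adjusted p 0.0386), whose own dye-corrected median was 0.251. The ribosomal protein call was lost without 11 wk replicate 2 (adjusted p 0.0505), which left 1 list.

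The linear trend asked whether the lines drew apart or together with age. In 6 lists the ratio fell with age, and these were lists of energy metabolism, stress and translation. Mitochondrial respiration had a median of -0.0081 per week (11 of 42 genes above 0, adjusted p 0.00114, and adjusted p = 0.109 with an estimated correlation), with UQCRQ at -0.052 per week (SE 0.0148) and NDUFA9 at -0.056 (SE 0.0198). Fatty acid synthesis had -0.0069 per week (8 of 28 above 0, adjusted p 0.0213, and adjusted p = 0.449 with an estimated correlation), triglyceride storage -0.010 (7 of 19, adjusted p 0.0213, and adjusted p = 0.449 with an estimated correlation) and sterol synthesis -0.0098 (5 of 15, adjusted p 0.0213, and adjusted p = 0.109 with an estimated correlation). Immediate early and stress genes had -0.013 per week (5 of 18, adjusted p 0.0106, and adjusted p = 0.449 with an estimated correlation), with the chaperones HSPA2 at -0.063 (SE 0.0234) and HSPA8 at -0.058 (SE 0.0307), and ribosomal proteins -0.0073 (12 of 44, adjusted p 0.011, and adjusted p = 0.541 with an estimated correlation).

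limma called 0 features for the trend, with 366 at an unadjusted p under 0.05, and adjusted over the list alone 0 genes of the 6 lists passed, as over all features. The smallest p of named genes belonged to the membrane glutathione transferase MGST1 at -0.092 per week (SE 0.0219), whose ratio was 0.58 at 1 wk and -0.38 at 11 wk, GSTA2 at -0.038 (SE 0.0090) and the splicing gene LUC7L2 at 0.075 (SE 0.0194), each with an adjusted p of 1. FASN changed by -0.016 per week (SE 0.012), SCD by -0.020 (SE 0.0194), ACACA by 0.0060 (SE 0.0107), THRSP by -0.058 (SE 0.0250), PPARG by -0.046 (SE 0.0288) and ADIPOQ by 0.017 (SE 0.0138), none of them called. With 1 array left out in turn, FASN ranged over -0.024 to -0.0058, SCD over -0.030 to -0.0099, ACACA over 0.0010 to 0.011, THRSP over -0.073 to -0.028, ADIPOQ over 0.012 to 0.026 and PPARG over -0.065 to -0.024. Of the 6 list calls, 4 were lost without the age of 1 wk, where the adjusted p-values were 0.178 for mitochondrial respiration, 0.644 for fatty acid synthesis, 0.942 for triglyceride storage and 0.509 for sterol synthesis. Without the 3 arrays with shifted liver genes (1 wk replicates 2 and 4 and 5 wk replicate 1) the slope was near 0 in fatty acid synthesis (-0.00048 per week, adjusted p 0.982) and triglyceride storage (0.00036, 0.982). Mitochondrial respiration stood at -0.011 (adjusted p 0.00241, and adjusted p = 0.326 with an estimated correlation) and ribosomal proteins at -0.013 (0.00241, and adjusted p = 0.611 with an estimated correlation). All arrays of 1 wk kept without those 3 arrays had LL in the 647 channel, so line and dye are not separated at 1 wk. These slopes therefore cannot show whether the fall is gone. Without only the 2 arrays with high liver genes, mitochondrial respiration passed with an estimated correlation too (-0.010, adjusted p = 0.0382). In that setting fatty acid synthesis lost its call (-0.0043, adjusted p 0.131). The hepatocyte list was called upward there (0.012, adjusted p 0.000157, and adjusted p = 0.296 with an estimated correlation). With each array's own dye bias taken off, the trend calls of ribosomal proteins (-0.0034, adjusted p 0.388) and triglyceride storage (-0.0099, 0.109) ended. The matrix list was then called upward (0.0061, adjusted p 0.0393, and adjusted p = 0.333 with an estimated correlation). These 3 settings were chosen after seeing the data. Single arrays mattered as well. Without 1 wk replicate 4 only 3 lists were called, and triglyceride storage (0.497), fatty acid synthesis (0.0672), sterol synthesis (0.0507), stress genes (0.0615) and ribosomal proteins (0.0615) lost their calls. Fatty acid synthesis also lost its call without 1 wk replicate 2 (0.113), 9 wk replicate 2 (0.0511), 9 wk replicate 4 (0.0749) or 11 wk replicate 4 (0.0525), and triglyceride storage without 3 wk replicate 1 (0.0574), 3 wk replicate 4 (0.0533), 9 wk replicate 2 (0.0645), 11 wk replicate 3 (0.08) or 11 wk replicate 4 (0.0696). Sterol synthesis lost its call without 1 wk replicate 3 (0.0613), 9 wk replicate 1 (0.0517) or 11 wk replicate 1 (0.217), and ribosomal proteins without 1 wk replicate 3 (0.608), 3 wk replicate 2 (0.17) or 11 wk replicate 4 (0.128). Slopes were also weaker without 11 wk replicate 4, at -0.0041 for sterol synthesis, -0.0051 for mitochondrial respiration and -0.0081 for stress genes.

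The interaction test asked whether the line difference of a gene differed between ages. Among named genes the smallest p belonged to NECAB2, whose ratio was -0.43 at 7 wk and between -0.04 and 0.01 at the other ages (SE 0.0614 each), DISP1, a gene of hedgehog release, at 0.25 at 1 wk, -0.50 at 7 wk and 0.02 at 11 wk (SE 0.103 each), and GSTA2 at 0.33 at 1 wk and -0.14 at 7 wk (SE 0.0755 each), each with an adjusted p of 1. limma called 0 features, with 342 at an unadjusted p under 0.05. Among scores of the 30 lists, each the mean of a list's genes on an array, the interaction had an adjusted p of 0.981 for every list, so this test, unlike camera's for the trend, called no list.

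The dye effect compared one dye orientation with the other and was taken as technical, a choice the repeated clones did not settle. limma called 4324 features, 2072 above 0 and 2252 below, with 6115 at an unadjusted p under 0.05. Among the called were the cytokine gene IL1B at -0.43 and LRRN4 at -0.31, while PPARG at -0.25 was not called (adjusted p 0.0665). The ribosomal protein list had a dye median of -0.24. With the ratios turned by the dyes, these would be line differences. Then 5358 features would be called in the mean over ages, 209 in the trend, 507, 377, 1281, 2040, 1386 and 631 at the 6 ages from 1 to 11 wk, and 703 in the interaction. The extracellular matrix list would then have a median of -0.07 (adjusted p 0.22) and the ribosomal protein list -0.24 (adjusted p 2.51e-08), with 0 lists called with an estimated correlation in any comparison.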

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

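The tests of liver RNA, of a line difference shared by the birds of 1 wk, of dye bias left in the mean and of muscle RNA were chosen only after the result was seen. In 18 of 262 groups of 4 arrays 1 array lay far from the other 3, where chance gives about 1 in 20, or 13.1. Values are dye-corrected log2 ratios.

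The hepatocyte list, whose genes encode plasma proteins and liver enzymes, stood far apart on single arrays, with a median of 0.508 on 5 wk replicate 1, against -0.035 to 0.020 on the other 3 arrays, and of 0.877 on 1 wk replicate 2. The deposited ratios of its abundant genes on 1 wk replicate 2 and 5 wk replicate 1 were 4.07 and 3.68 for ALB, 4.18 and 2.04 for FGB and 2.01 and 1.23 for TTR, and another list holds 8 of the 32 genes. A position effect is argued against by the 203 neighbouring spots, with medians of 0.0491 and -0.0181. On 1 wk replicate 4 the list's median was -0.311, with dye-corrected ratios of -1.83 for ALB and -1.06 for FGB. Over the list its rank correlation with 1 wk replicate 2 was -0.712, so it carried the pattern reversed. This argues against a line difference shared by all birds of 1 wk as the whole cause, but such an array cannot exclude a smaller one. ALB also stood at 1.17 on 1 wk replicate 3 and 1.02 on 7 wk replicate 2. As a hypothesis, liver RNA in single samples may account for the pattern, since 1 wk replicate 2 and 5 wk replicate 1 ranked the list's genes alike (rank correlation 0.868). A difference between single birds may do so too and was not tested. Such samples touch the hemostasis and hepatocyte lists at 1 wk, which stood at -0.024 and -0.11 without these 2 arrays.

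Skeletal muscle genes stood apart on 7 wk replicate 4, where the list's median was -0.258, against -0.042 to -0.021 on the other 3 arrays. The deposited ratios there were -2.26 for TNNT3 and -1.17 for ACTA1, but 0.35 for TNNC2 and 0.0594 for PVALB, and another list holds 2 of the 35 genes. A position effect is argued against by the 189 neighbouring spots, with a median of -0.0282. As a hypothesis, muscle RNA in 1 sample may account for the call at 7 wk, since the list stood at -0.0107 without that array, although TNNC2 and PVALB go against it. A difference between the lines at 7 wk stays open and untested.

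The matrix and ribosomal protein lists were higher in the numerator line in the mean over ages, although not at 5 wk for the matrix (median -0.0088) nor at 7 and 9 wk for ribosomal proteins (-0.0063 and -0.057). Dye bias left in the mean is argued against as the whole cause, since it predicts 0.0023 for the matrix list and 0.00841 for ribosomal proteins, against medians of 0.0412 and 0.0643. With each array's own dye bias taken off, the medians were lower, 0.0325 for the matrix list and 0.0449 for ribosomal proteins. They fell by more than the prediction, so dye bias may carry part of both. Both lists stayed called (adjusted p 2.37e-05 and 8.69e-05, and adjusted p = 0.0801 and 0.744 with an estimated correlation). Genes of a list moving together by chance could not be excluded. With the real split counted, 9 of 100 splits gave the matrix list a median as large in size (highest other 0.0561). For the ribosomal proteins 8 of 100 did (highest other 0.103). As a mean score per array the matrix list stood at 0.0758 (adjusted p 0.0243) and ribosomal proteins at 0.0863 (0.408), and a line difference may underlie both and stays open.

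Further list medians stood apart on single arrays. Those on 1 wk replicates 2 and 4 and 5 wk replicate 1 lie on the arrays with shifted liver genes. They need not be independent of the hepatocyte result. Another list holds 3 of the 11 thyroid axis genes and 6 of the 24 adipokine genes. The sterol synthesis list was at 0.163 on 5 wk replicate 1, against -0.0083 to 0.011 on the other arrays of its age. Adipokines were at 0.0824 on 1 wk replicate 2, against -0.050 to -0.044, at -0.0695 on 3 wk replicate 2, against 0.016 to 0.025, and at 0.0594 on 11 wk replicate 4, against 0.018 to 0.021. The thyroid axis was at 0.177 on 1 wk replicate 2, against -0.039 to -0.0036. Extracellular matrix genes were at 0.117 on 1 wk replicate 4, against 0.0023 to 0.0072. Mitochondrial respiration was at 0.0656 on 3 wk replicate 2, against -0.00041 to 0.0011. The interferon response was at 0.0448 on 9 wk replicate 3, against -0.023 to -0.014. On 11 wk replicate 1, B cell genes were at -0.106, against -0.012 to -0.0056, and leukocyte genes at -0.0846, against -0.0044 to 0.0058. Erythrocyte genes were at 0.15 on 11 wk replicate 4, against -0.068 to -0.031.

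Single genes stood apart as well. SULT6B1L was at 1.5 on 3 wk replicate 2, against 0.25 to 0.36 on the other arrays of its age, at 0.0237 on 5 wk replicate 2, against 0.83 to 0.94, and at 0.436 on 9 wk replicate 1, against 0.31 to 0.32. FASN was at -0.0482 on 5 wk replicate 3, against -0.22 to -0.19, and THRSP at 0.29 on 11 wk replicate 1, against -0.29 to -0.22.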

How the results depend on the processing

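The tests chosen only after the results were seen are those with the names as given, ratios turned by dye, position loess, each array's own dye bias taken off, and the arrays with shifted liver genes left out. Direction and side of the threshold were kept in 4532 comparisons of single genes and lists with the settings fixed beforehand. In 17 a call was gained, in 90 one was lost and in 44 the sign turned. With the settings chosen afterwards these numbers were 851, 23, 64 and 140. Counts of features and of lists stayed within 1.5 times the reported count in 590 comparisons with the former and 102 with the latter settings, and left that range in 41 and 42. A count of 0 that stayed 0 is among those kept, and so is a gene called in neither fit. Fits with 1 array left out also share all their other arrays. These numbers therefore do not measure how firm a call is. The replicate block changed no count of lists. Whether the numbers pair arrays is not settled by the data: over 60 pairs with one number the mean correlation across spots was -0.0623, against -0.090 for the other number of the same dye orientation, since taking off the dye effect sets such arrays apart. Of 24 arrays 16 lay nearer their own number than that other one, and 73 of 1024 numberings gave a mean as high (highest other -0.051), a test chosen after the result was seen. Without scanner intensities the limit set by signal over background is unknown. Below, a list is said to turn when camera's direction turned, and its median, given in brackets, may keep its sign. For the single spots and the ages or arrays left out, fewer values enter each estimate by construction. With the names as given a symbol stands for other spots, and with ratios turned by dye the mean over ages carries the dye effect. For all other settings the cause was not tested.

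With arrays scaled to one spread, lists called were 1 at 5 wk and 1 at 9 wk. ACACA (-0.016) and ADIPOQ (0.0058) turned in the mean over ages. With array weights, features called were 2 in the mean over ages and 182 at 3 wk, and lists called were 2 in the trend, 1 at 5 wk and 1 at 9 wk. ACACA (-0.026) and ADIPOQ (0.017) turned in the mean over ages. With spots kept single, features called were 1 in the mean over ages. Without the age of 1 wk, features called were 1 in the mean over ages, and lists called were 2 in the trend. FASN (-0.018), ADIPOQ (0.041) and PPARG (-0.033) turned in the mean over ages. ADIPOQ (-0.0030) turned in the trend. Without the age of 3 wk, the sign turned in the mean over ages for FASN (-0.0055). Without the age of 5 wk, features called were 2 in the mean over ages. ACACA (-0.019) turned in the mean over ages. Without the age of 9 wk, lists called were 3 in the trend. FASN (-0.013), ACACA (-0.026) and THRSP (0.0011) turned in the mean over ages. ACACA (-0.0021) turned in the trend. From the 4 arrays of 7 wk alone, features called were 0 at 7 wk. With an estimated correlation, lists called were 0 in the mean over ages, 0 in the trend, 0 at 1 wk, 0 at 3 wk, 0 at 5 wk, 0 at 7 wk and 0 at 11 wk.

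With 1 array left out in turn, features called ranged over 0 to 100 in the mean over ages, 0 to 1 at 1 wk, 0 to 18 at 3 wk, 0 to 5 at 5 wk and 0 to 2 at 7 wk. The number of lists called ranged over 3 to 7 in the trend, 4 to 9 at 1 wk, 0 to 4 at 3 wk, 0 to 3 at 5 wk, 1 to 2 at 7 wk and 1 to 3 at 11 wk. Ranges of single results that turned were FASN -0.011 to 0.030 in the mean over ages, SCD -0.090 to 0.17 at 1 wk, ACACA -0.013 to 0.016 in the mean over ages, THRSP -0.019 to 0.61 at 1 wk, ADIPOQ -0.030 to 0.019 in the mean over ages and PPARG -0.012 to 0.089 in the mean over ages. Further ranges of single results that turned were hemostasis list -0.024 to 0.11 at 1 wk, hepatocytes list -0.12 to 0.33 at 1 wk and skeletal muscle list -0.11 to -0.011 at 7 wk.

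With the names as given, lists called were 0 in the mean over ages, 0 in the trend, 0 at 1 wk, 0 at 3 wk, 0 at 5 wk, 0 at 7 wk and 0 at 11 wk. ADD3 (-0.022), FASN (-0.044), ACACA (-0.062), THRSP (0.031), HSD17B7 (0.012), EBF3 (-0.048), RARRES2 (-0.0029), POSTN (-0.023) and ATP5O (-0.035) turned in the mean over ages. IRF1 (-0.0091), IL2RG (0.021), IL2RA (-0.10), ARHGDIB (-0.011), CD40 (-0.0098), IL1B (-0.036), HBBA (-0.038), EPB41 (0.068) and TRDN (0.048) turned in the mean over ages. LMOD1 (-0.050), LRRN4 (-0.014), LECT2 (0.0038), CPA1 (0.034), S100B (0.052), SOX10 (-0.053), RPL17 (-0.0079) and the skeletal muscle list (-0.0042) turned in the mean over ages. GSTA2 (0.0067), LUC7L2 (-0.0053), THRSP (0.0079), ADIPOQ (-0.0064), PPARG (0.0068), the triglyceride storage list (0.0076), the mitochondrial respiration list (0.0031) and the ribosomal proteins list (0.0011) turned in the trend. GSTA2 (-0.012), SCD (-0.053), the fatty acid synthesis list (-0.013), the triglyceride storage list (-0.017), the mitochondrial respiration list (-0.024), the hepatocytes list (-0.035) and the ribosomal proteins list (0.0041) turned at 1 wk. RBBP6 (0.079) turned at 5 wk. The extracellular matrix list (-0.023) turned at 7 wk. PHLDA2 (0.084) turned at 9 wk. GPX3 (-0.053), GPR183 (-0.18) and POSTN (-0.030) turned at 11 wk.

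With ratios turned by dye, features called were 5358 in the mean over ages, 209 in the trend, 507 at 1 wk, 377 at 3 wk, 1281 at 5 wk, 2040 at 7 wk, 1386 at 9 wk, 631 at 11 wk and 703 in the interaction, and lists called were 1 in the mean over ages, 0 in the trend, 2 at 1 wk, 0 at 3 wk, 1 at 5 wk, 1 at 7 wk, 2 at 9 wk and 1 at 11 wk. ADD3 (-0.20), SULT6B1L (-0.21), GPR183 (-0.49), FASN (-0.046), ACACA (-0.15), ADIPOQ (0.061), PPARG (-0.25), FADS1 (-0.030) and SLC25A20 (-0.046) turned in the mean over ages. ACADL (0.039), EBF3 (-0.074), RARRES2 (-0.076), SERPINE2 (-0.088), THRB (0.18), IGF2BP3 (-0.036), POSTN (-0.068), FN1 (-0.066) and CCND1 (-0.11) turned in the mean over ages. KIF2C (0.0043), JUN (-0.23), B2M (-0.11), ARHGDIB (-0.12), CD40 (-0.039), IL1B (-0.43), HBBA (-0.0076), EPB41 (0.090) and LMOD1 (-0.067) turned in the mean over ages. CALB2 (0.054), LRRN4 (-0.31), LECT2 (0.11), S100B (0.17), SOX10 (-0.045), RPS24 (-0.19), RPL17 (-0.23), the extracellular matrix list (-0.067) and the ribosomal proteins list (-0.24) turned in the mean over ages. LUC7L2 (-0.022), ACACA (-0.012), ADIPOQ (-0.0031) and the ribosomal proteins list (0.0010) turned in the trend. GSTA2 (-0.065), ADIPOQ (0.15), the mitochondrial respiration list (-0.052), the smooth muscle list (-0.024) and the ribosomal proteins list (-0.25) turned at 1 wk. EIF1B (0.059), the extracellular matrix list (-0.050) and the ribosomal proteins list (-0.097) turned at 3 wk. CES1L1 (-0.13), the hepatocytes list (-0.15) and the ribosomal proteins list (-0.34) turned at 5 wk. NECAB2 (0.13) and the extracellular matrix list (-0.039) turned at 7 wk. GPX3 (-0.32), GPR183 (-0.51), POSTN (-0.21), the extracellular matrix list (-0.094) and the ribosomal proteins list (-0.19) turned at 11 wk.

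After position loess, features called were 1 in the mean over ages and 0 at 7 wk, and lists called were 1 at 9 wk. ACACA (-0.0064) and ADIPOQ (0.0079) turned in the mean over ages. ACACA (-0.0023) turned in the trend. SCD (-0.00069) turned at 1 wk. After position loess and plate medians, features called were 3 in the mean over ages and 0 at 7 wk, and lists called were 1 in the trend and 1 at 9 wk. ACACA (-0.026) and ADIPOQ (0.0042) turned in the mean over ages. SCD (-0.059) turned at 1 wk. After position loess and without 5 wk replicate 2, features called were 27 in the mean over ages. ACACA (-0.017), ADIPOQ (0.0076) and LCP1 (0.012) turned in the mean over ages. With each array's own dye bias taken off, features called were 0 in the dye effect, and lists called were 0 at 3 wk and 1 at 9 wk. ACACA (-0.0083) turned in the mean over ages. Without the 2 arrays with high liver genes, lists called were 0 at 5 wk. FASN (-0.0070) and ACACA (-0.0077) turned in the mean over ages. SCD (-0.0019), the hemostasis list (-0.024) and the hepatocytes list (-0.11) turned at 1 wk. Without the 3 arrays with shifted liver genes, lists called were 3 in the trend, 2 at 1 wk and 0 at 5 wk. FASN (-0.027), ACACA (-0.022) and PPARG (-0.075) turned in the mean over ages. FASN (0.0031), SCD (0.00096), PPARG (0.00021) and the fatty acid synthesis list (-0.00048) turned in the trend. FASN (-0.11), SCD (-0.25), PPARG (-0.24), the fatty acid synthesis list (-0.046) and the triglyceride storage list (-0.015) turned at 1 wk. All arrays of 1 wk kept in that setting had LL in the 647 channel, so its line effect at 1 wk is not separated from dye. The mean over ages and the trend in that setting carry the same limit. With each array's own dye bias and those 2 arrays taken off, lists called were 0 at 3 wk, 0 at 5 wk and 1 at 9 wk. FASN (-0.014), ACACA (-0.011) and PPARG (-0.0017) turned in the mean over ages. SCD (-0.023), the hemostasis list (-0.027) and the hepatocytes list (-0.11) turned at 1 wk. The hepatocytes list (0.0094) turned at 5 wk.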

Other observations

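The tests in this part on the features called without 5 wk replicate 2 were chosen only after the result was seen. Genes of several functions were called in the mean over ages once that array was left out, and all 100 kept the sign they had with 24 arrays. Higher in the numerator line were RAB7A, a GTPase of late endosomes, at 0.34 (adjusted p 0.0106), ERN1, a sensor of endoplasmic reticulum stress, at 0.51 (0.0213), the vitamin C transporter SLC23A1 at 0.23 (0.0265) and the collagen gene COL18A1 at 0.15 (0.0363). Lower were PRKCD, a protein kinase C, at -0.25 (0.00552) and CALCA, which encodes calcitonin, at -0.27 (0.024). With all arrays none of these was called, and this array is the one of 24 whose omission gave the most calls. Named genes made up 38 of the 100, with 4 of the matrix list and 4 of the ribosomal protein list, and these examples were chosen after their values were seen.

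Of the unnamed features called in that setting, 27 were lower and 35 higher. All 27 of the lower spots lay in 1 column of blocks on the array, and 0 of the 35 higher ones did. After position loess and without 5 wk replicate 2, 27 features were called in the mean over ages, 22 higher and 5 lower, against 64 and 36 without the loess, so position on the array may account for part of them. The blocks of named features were not examined, so whether position plays a part in the lower PRKCD and CALCA was not tested.

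Splits of the arrays tested whether a result as large arises by chance. Each number of splits given includes the real one. For features, 0 were called in the mean over ages, the trend and the interaction, and the highest other counts were 1, 1 and 2. Every split reaches a count of 0, so the 100 of 100 splits with as many decide nothing, and the same holds for the single ages with 0. For the dye effect, 4324 features were called against a highest other of 2765. Only the real split reached that count, 1 of 100, the smallest share that 100 splits can give, so chance is unlikely there. For lists, chance is not excluded in the mean over ages (3 called, highest other 4, 17 of 100 splits). In the trend, 2 of 100 splits reached camera's count with the preset correlation (6 called, highest other 6). That share lies under 0.05 without correction for the number of comparisons split, so chance is less likely there but not excluded. With an estimated correlation 0 lists were called in the trend (smallest adjusted p 0.109), although mitochondrial respiration passed without the 2 arrays with high liver genes (-0.0102, adjusted p 0.0382), and the mean scores of the 6 lists had adjusted p-values of 0.537 to 0.877. At single ages there are 3 splits, too few for a share under 0.05. Features called from the youngest age to the oldest were 0, 0, 0, 1, 0 and 0, the highest others 0, 0, 198, 0, 0 and 0, and the splits with as many 3, 3, 3, 1, 3 and 3. Lists called were 7, 3, 2, 2, 0 and 2, the highest others 4, 1, 1, 1, 0 and 2, and the splits with as many 1, 1, 1, 1, 3 and 2. The 198 features of 1 other split at 5 wk came from a grouping of these 4 arrays other than the lines. What separates them, a single array included, was not tested.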
